A study of Mus musculus with 4 samples.

How the data were processed

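CD4 T cells sorted as CD45+ TCRb+ CD4+ from the colon lamina propria of male B6 mice aged 6 weeks were profiled by inDrops, per the labels' protocols. Tissue was digested with collagenase and dispase, RNA was captured with oligo dT primers, and libraries were made by linear amplification through in vitro transcription and sequenced on a NextSeq500. The labels give 4 samples in 1 group. The deposited values are counts per barcode and gene in 1 table, made by the authors with TopHat2 and SAMtools and the mm10 build, per the submitters' processing notes, which name these without versions or roles. The counting tool, the collapse of molecular identifiers, the gene annotation and any filter on barcodes are not given in the sources used here. The values are called counts for that reason, and intervals and floors cover counting error only.

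The barcodes of the table carry no sample, so the 4 samples could not be separated and the table was handled as 1 sample. The tests fixed for separable samples (edgeR's quasi-likelihood test, DESeq2, camera, fry, sample agreement and tests over samples) were not used for this reason. The fallback fixed with them was used: CPM on both sides of each comparison, with a log2 ratio and its exact conditional 95% interval. The cell filters, clustering settings, gates, gene lists, markers, naming of genes and most alternatives were chosen before the data were examined. Gene symbols were matched to GENCODE vM21, which uses the same build, and 25033 of 25724 symbols (97.3%) matched. A total of 8251 genes had 0 counts.

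Cells were kept with at least 500 counts, at least 200 genes and under 20% mitochondrial counts, and doublets called by Scrublet (scanpy 1.11.5, scikit-image 0.26.0) were left out. Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes without T cell receptor, immunoglobulin, ribosomal, mitochondrial and sex-linked genes, 20 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9). Neighbours were found with the exact kd-tree of scikit-learn 1.9.0, since other methods varied between runs. A cluster was named when at least 3 markers of 1 list, and more than of any other list, were among its 50 genes of highest fold that had at least 50 counts and were detected in at least 10% of its cells. It stayed unnamed where another list had more markers among its 10 leading genes. It also stayed unnamed where none of those 10 genes was a marker of its list and its median depth was below that of all cells divided by 3. The marker lists were Treg, Th17, Th1, Th2, Tfh, naive, cytotoxic, cycling, interferon, CD8 T, gamma delta T, ILC or NK, B or plasma, myeloid, epithelial, stromal or endothelial, and erythroid.

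Some choices were made after results were seen. Clustering on genes scaled to unit variance was run first, and the unscaled version was kept after both were seen. The detection minimum for naming was coded at 10%, and 4 values were tried. The minimum was moved to 20% for a time and then put back. The epithelial-like cells were left out as an alternative, 3 gates on Gata3 or Ikzf2 were added, and counts were capped at 1 because counts varied more than Poisson counts would. The rule for lists was tightened so that a gene gives no ratio where both sides hold at most 3 counts or where a side of 0 gives no bound. Further random draws of thinning and of the split of each cell's counts into equal parts were added, 10 of each.

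Cells with at least 1 count of Foxp3 were compared with cells without. Cells with Il17a were to be compared with cells with Ifng, where each side held at least 10 cells. A side of 0 counts was set to a floor of 3 counts, which gives a bound. For each gene list, members with at least 10 counts entered a median log2 ratio. Its interval came from 500 Poisson draws, and its percentile from 10000 random lists matched on total counts in 20 bins, as a description of this table. Named genes are the 12 highest and 12 lowest ratios among genes with at least 50 counts whose interval leaves out 0, and up to 4 members of each list that lay outside the middle 95% of random lists. Those members were taken by the size of the ratio over its interval width, since no p-value exists. Fixed markers were always included. Gate genes, ribosomal, mitochondrial, immunoglobulin, T cell receptor and predicted genes were left out. Some genes, 1 gene list and 1 other planned comparison are not reported here.

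The lists were Treg core signature, tissue or effector Treg, Helios or GATA3 Treg program, Th1 and cytotoxic, Th2 cytokines and receptors, naive and circulating, Tfh, TCR and immediate early, dissociation stress, cell cycle, interferon response, tissue residency and homing, glycolysis, lipid and cholesterol metabolism, B or plasma, myeloid, epithelial, and CD8, gamma delta, ILC or NK. Some genes are in several lists, for example Gata3 and Klrg1. Marker detection was compared after thinning each cell to 500 counts, between the 327 and 714 cells set by all counts. For ratios after thinning, cells were instead put on a side by their thinned counts, which set 192 Foxp3-positive against 849 Foxp3-negative cells.

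The ratio step was tested on simulated data for the Foxp3 comparison (4696 genes). Intervals covered the simulated log2 change in 96% of genes for 1, 93.0% for -1, 98% for 2 and 97.6% for -2. The interval left out 0 for 94%, 81.4%, 100% and 97.6% of those genes, and for 4.83% of 4511 unchanged genes. In the list step (9306 genes, lists of 20 genes), 20 of 20 raised lists lay above the middle 95% and 95 of 100 unchanged lists lay inside it. Simulated counts were Poisson, while the measured ones vary more, so intervals here are too narrow. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.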

Results

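Single-cell RNA profiles were collected by inDrops, a method that encapsulates single cells in droplets with barcoded reverse transcription primers, from CD4 T cells of the mouse colon. Live cells from the colon lamina propria, the connective tissue layer under the gut epithelium, were sorted as CD45+ TCRb+ CD4+. The labels list 4 numbered samples in 1 group, named Btheta_colon, all from male B6 mice aged 6 weeks and all under 1 library name. The data hold 1 table of counts for 1985 barcodes and 25724 gene symbols, and the barcodes carry no sample. The table was therefore treated as 1 sample without replicates, and no p-value is given. The series states no question beyond profiling these cells, so the comparisons were made between kinds of cell within the table.

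The table held 1690867 counts, with 0 to 13023 per barcode and a median of 710. A total of 1071 barcodes had at least 500 counts, 1058 of those had at least 200 detected genes, and 1050 also had under 20% mitochondrial counts. Scrublet called 9 of the 1050 as doublets (0.857%), which left 1041 cells with 1534602 counts. The median cell had 1234 counts (quartiles 962 and 1721, range 501 to 13023), 612 detected genes and 4.44% mitochondrial counts. At this depth a gene with 0 counts over all 1041 cells could still be present at up to 1.95 CPM, the usual scale on which counts are set against the total. All intervals are 95% intervals and cover counting error only.

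**Figure D1:**
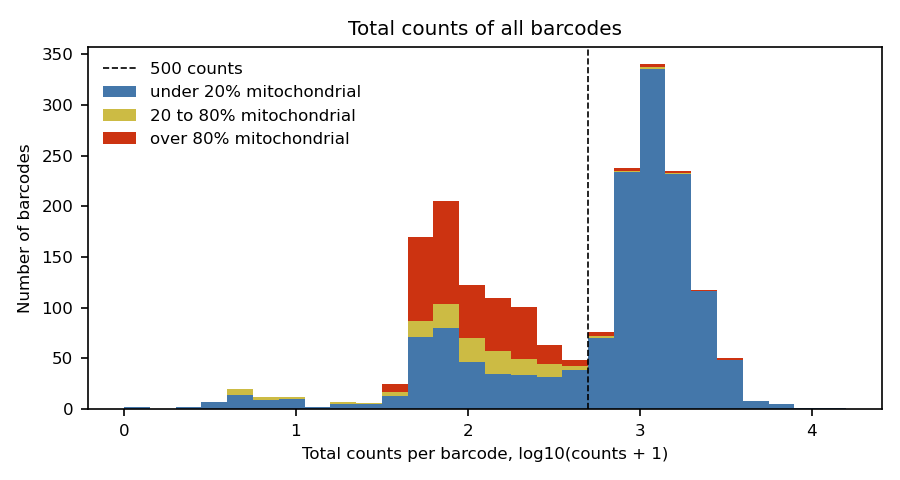
Number of barcodes by total counts per barcode, on a log10(counts + 1) axis, stacked by the share of mitochondrial counts (under 20%, 20 to 80%, over 80%). The dashed line marks the 500-count minimum, which 1071 of the 1985 barcodes passed.

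Colon CD4 T cells separated into 10 clusters, in which cells carrying the transcript of Foxp3, the lineage factor of regulatory T cells (Tregs), stood beside naive-like, Th1-like and cycling-like cells. A Treg-like cluster of 192 cells made up 18.4% of cells (exact interval 16.1 to 20.9) and was led by Penk, the enkephalin precursor, with Cd83, Ikzf4, Tnfrsf9 and Klrg1. A naive-like cluster of 107 cells (10.3%, 8.50 to 12.3) was led by Ccr7, which directs T cells to lymph nodes, with Igfbp4, Satb1 and Bcl2. A Th1-like cluster of 78 cells (7.49%, 5.97 to 9.26) was led by Tbx21, which encodes the Th1 factor T-bet, and also held Nkg7. In this cluster Tbx21 was detected in only 12.8% of cells and Nkg7 in 37.2%. A cycling-like cluster of 41 cells (3.94%, 2.84 to 5.31) carried Birc5, Ccna2 and Rrm2, and had a median of 2767 counts. Another 609 cells (58.5%, 55.4 to 61.5) fell in 5 clusters that met no naming rule. These shares depended on the clustering: the Treg-like share ran from 0% to 51.5% and the naive-like share from 0% to 32.1% over 11 alternative settings. The Th1-like share ran from 0% to 16.9% and was 0% in 7 of them, and the cycling-like and epithelial-like shares were 0% in 4 each.

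Among the 5 unnamed clusters, cluster 2 (158 cells) was led by Lyn, Cd74, Dusp10, Npnt, Cpm and Areg, the last encoding the epithelial repair factor amphiregulin. Gata3, which encodes a factor of Th2 cells and of some tissue Tregs, was detected in 87.3% of its cells. The myeloid genes Lyz2 (188 CPM) and H2-Aa (235 CPM) were detected in 1.90% and 2.53% of them, and with no detection minimum for leading genes this cluster (15.2% of cells) was named myeloid-like. Cluster 6 (186 cells) was led by genes that included Gzmb, Mmp9 and Ccr2, and Gata3 was detected in 22.6% of its cells. Il10, the gene of an anti-inflammatory cytokine, was detected in 46.4% of the Treg-like cluster, 43.0% of cluster 2 and 43.0% of cluster 6. It was among the markers that named the Treg-like cluster, so its share there is not independent of the name. The other unnamed clusters held 82 cells (cluster 3, with Nkg7 among its leading genes), 127 cells (cluster 4) and 56 cells (cluster 7). No cluster was named from the marker lists for Th17, Th2, Tfh, cytotoxic, interferon, CD8 T, gamma delta T, ILC or NK, B or plasma, myeloid, stromal or endothelial, and erythroid cells.

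A cluster of 14 cells (1.34%, 0.737 to 2.25) was epithelial-like although the sort selected CD45+ T cells. Its leading genes were Car1, Krt20, Klk1, Guca2a and Muc2, which are expressed in colon epithelium. Few of the cells carried them, with Car1 and Krt20 in 2 cells each and Muc2 in 5. Markers of other cell types were also present, with the stromal genes Sparc in 6 cells and Col1a1, Col3a1 and Dcn in 3 each, and the myeloid genes C1qa and Csf1r in 2 each. Cd4 was detected in 0 of the 14 cells (upper limit 23.2%) and Cd3g in 1, and their median was 3871.5 counts. Muc2, the gel-forming mucin, was also unevenly spread, with 869 of its 1278 counts in 1 cell. Values for the comparison by Foxp3 are therefore also given without these 14 cells, a choice made after seeing the data.

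Foxp3 (chromosome X, 7573644 to 7595245, protein coding, mm10) was detected in 327 of 1041 cells, or 31.4% (28.6 to 34.3). The share was 52.1% (44.8 to 59.3) in the Treg-like cluster, 48.7% (40.7 to 56.8) in cluster 2 and 46.2% (38.9 to 53.7) in cluster 6. The other cells of these clusters had no Foxp3 count at this depth and count as Foxp3-negative below. The share was 5.61% (2.09 to 11.8) in the naive-like cluster and 8.97% (3.68 to 17.6) in the Th1-like cluster. The median depth was 1169.5 counts in the Treg-like and 1102 in the naive-like cluster. With every cell thinned to 500 counts, Foxp3 was detected in 34.4% (27.7 to 41.6) of Treg-like and 3.74% (1.03 to 9.30) of naive-like cells.

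**Figure D2:**
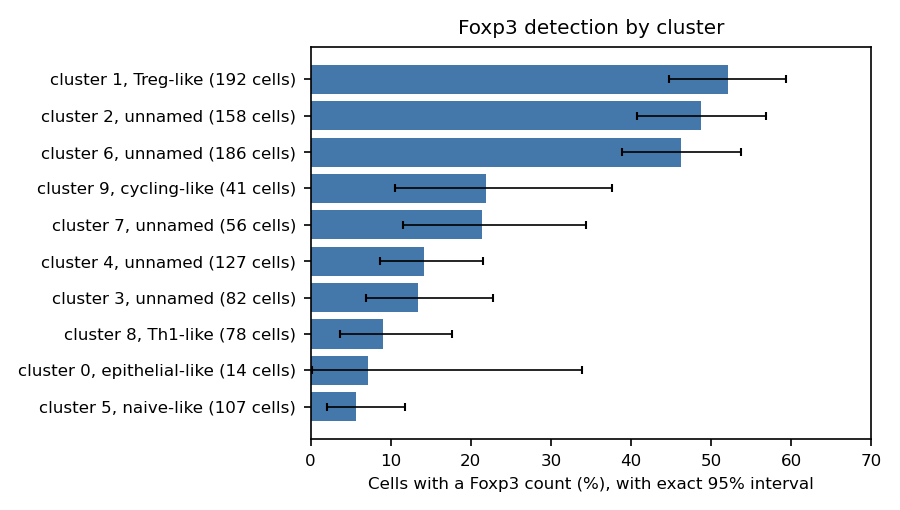
Percentage of cells with at least 1 Foxp3 count in each of the 10 clusters, unthinned, with exact 95% binomial intervals as error bars and cell numbers in the axis labels. The Treg-like cluster and clusters 2 and 6 lie at 46.2% to 52.1%, above the naive-like cluster at 5.61%.

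Foxp3-positive cells carried higher levels of the genes that mark and arm regulatory T cells. Of 26 measured members of the Treg core signature, 24 were higher in the 327 Foxp3-positive than in the 714 Foxp3-negative cells, 18 of them by at least 1.5-fold. The median log2 ratio of the list was 0.88 (0.77 to 0.97), above all 10000 random gene lists matched on expression. Ctla4, an inhibitory receptor, stood at 1904 CPM against 909 CPM (log2 ratio 1.07, 0.94 to 1.2). Ikzf2, which encodes Helios, stood at 874 against 363 CPM (1.27, 1.07 to 1.47), and Tnfrsf4, which encodes OX40, at 805 against 368 CPM (1.13, 0.92 to 1.34). Il2ra, the high-affinity chain of the IL-2 receptor, stood at 294 against 154 CPM (0.94, 0.60 to 1.27), and the costimulatory receptor gene Icos at 1898 against 1032 CPM (0.88, 0.75 to 1.01). In mm10 these genes lie at chromosome 1, 60887000 to 60915832 (Ctla4), and chromosome 1, 69531214 to 69687245 (Ikzf2), and both are protein coding. The sides had similar depth, with medians of 1304 and 1213.5 counts. With each count capped at 1 per cell and gene, a version that is not moved by a few cells of high counts, the list median was 0.71.

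Effector and tissue Treg genes were higher in the same cells. In the tissue or effector Treg list 19 of 23 measured members were higher (median 0.64, 0.53 to 0.81, above all random lists). Il10 stood at 947 against 373 CPM (1.35, 1.15 to 1.54) and Gzmb, which encodes the cytotoxic protease granzyme B, at 833 against 320 CPM (1.38, 1.17 to 1.59). Maf, a transcription factor that drives Il10, stood at 1600 against 1027 CPM (0.64, 0.51 to 0.77), and S100a6 at 2306 against 1495 CPM (0.63, 0.51 to 0.74). With the sides instead set by Treg-like clusters, found on a random part of the counts and compared with all other cells on the rest, S100a6 stood at -0.070. In the Helios or GATA3 Treg list 10 of 14 were higher (median 0.63, 0.33 to 0.88, above all random lists), among them Klrg1 (0.99, 0.78 to 1.2), Fgl2 (0.91, 0.70 to 1.11) and Tnfrsf9 (0.89, 0.66 to 1.12). Most members of this list, Klrg1 and Tnfrsf9 among them, are also in the Treg core list, so its median is no separate support. Gata3 itself differed less, at 1681 against 1364 CPM (0.30, 0.18 to 0.43), and its capped and thinned intervals included 0.

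Genes of T cell receptor signalling and immediate early response were modestly higher. In this list 16 of 21 measured members were higher (median 0.26, 0.18 to 0.42), above 98.9% of random lists. Examples were the receptor-induced nuclear receptor gene Nr4a1 (0.80, 0.59 to 1.02), and Nfkbia (0.63, 0.53 to 0.73) and Tnfaip3 (0.66, 0.47 to 0.84), which restrain NF-kB. The capped interval of Nfkbia included 0. The dissociation stress list, which shares immediate early genes with it, lay at -0.05 (-0.17 to 0.14, 28.5th percentile). The Tfh list had 5 of 6 measured members higher (median 0.79, 0.30 to 1.06, 99.8th percentile), including Tox (0.71, 0.35 to 1.06). After thinning the Tfh median was 0.14 and Tox was -0.71, so its direction was not settled at this depth.

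Naive and circulating T cell genes were lower in Foxp3-positive cells. In this list 13 of 16 members were lower (median -1.08, -1.60 to -0.75), below all 10000 random lists. Tcf7, which encodes the naive and memory T cell factor TCF-1, stood at 19.7 against 164 CPM (-3.06, -4.15 to -2.14), and Satb1 at 35.5 against 126 CPM (-1.82, -2.62 to -1.10). Ccr7 stood at 7.89 against 67.1 CPM (-3.09, -5.00 to -1.67) and Igfbp4 at 5.92 against 92.4 CPM (-3.96, -6.27 to -2.37). Cd27 went the other way, at 414 against 263 CPM (0.66, 0.39 to 0.92). After thinning the intervals of Cd27 (0.22, -0.33 to 0.74) and Ccr7 (-2.50, -7.86 to 0.11) included 0.

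Th1 genes were lower, with exceptions. In the Th1 and cytotoxic list 10 of 16 measured members were lower (median -0.39, -0.77 to -0.04, 1.69th percentile). Tbx21 stood at 15.8 against 57.4 CPM (-1.86, -3.14 to -0.79), Ifng at 15.8 against 54.5 CPM (-1.79, -3.07 to -0.71), and the chemokine gene Ccl5 at 35.5 against 126 CPM (-1.83, -2.63 to -1.12). Gzmb, also in this list, was higher. The capped and thinned intervals of Ccl5 and Ifng included 0, as did the thinned interval of the list (-0.50, -0.79 to 0.41). Il17a had 0 counts in Foxp3-positive and 35 in Foxp3-negative cells, at least 5.75-fold lower, and the capped bound, which stems from 9 cells, did not leave out 0. Il22 had 2 counts in all, too few for a ratio.

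Proliferation and interferon genes were lower on the Foxp3-positive side in the pooled counts. In the cell cycle list 16 of 20 measured members were lower (median -0.48, -0.60 to -0.27, 0.01st percentile), for example Hmgb2 (-0.49, -0.74 to -0.25) and Ube2c (-0.96, -1.79 to -0.20), while H2afz was higher (0.45, 0.27 to 0.64). In the interferon response list 12 of 17 were lower (median -0.48, -0.57 to -0.04, 0.19th percentile), with Isg15 at -1.18 (-2.21 to -0.26) and Bst2 at -0.80 (-1.53 to -0.11), while Ifi27l2a (0.92, 0.58 to 1.26) and Igtp (0.68, 0.30 to 1.07) were higher. The capped intervals of Hmgb2, Ube2c, H2afz, Isg15, Bst2 and Igtp included 0. After thinning H2afz was -0.12, and the intervals of Ube2c, Isg15, Bst2 and Igtp included 0. Neither list held throughout: the cell cycle median was 0.17 in cells at odd positions of the table and -0.82 in those at even positions, and the interferon median was -0.04 after thinning.

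The other lists fixed for T cell states lay inside the middle 95% of random lists. Tissue residency and homing stood at 0.07 (-0.12 to 0.30, 8 of 15 higher), glycolysis at 0.11 (-0.07 to 0.25, 9 of 16), and lipid and cholesterol metabolism at -0.13 (-0.47 to 0.03, 7 of 16). Th2 cytokines and receptors stood at -0.30 (-1.10 to 0.34, 4 of 9 higher), and at -0.78 (0.75th percentile) without the epithelial-like cluster. With capped counts these medians were 0.26 and -0.04. Of the lists for other cell types, B or plasma (0.37, -0.84 to 0.83, 3 measured genes) and CD8, gamma delta, ILC or NK (0.02, -0.85 to 0.61, 6 genes) lay inside that range. The epithelial list lay at -3.72 (-4.39 to -3.21, 8 of 8 lower, 2 of them at the floor), and only 1 of its genes was measurable without the 14 epithelial-like cells. The myeloid list lay at -0.82 (-1.42 to -0.45, 0.47th percentile, 4 of 6 lower), but at 0.44 with capped counts and 0.34 after thinning.

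**Figure D3:**
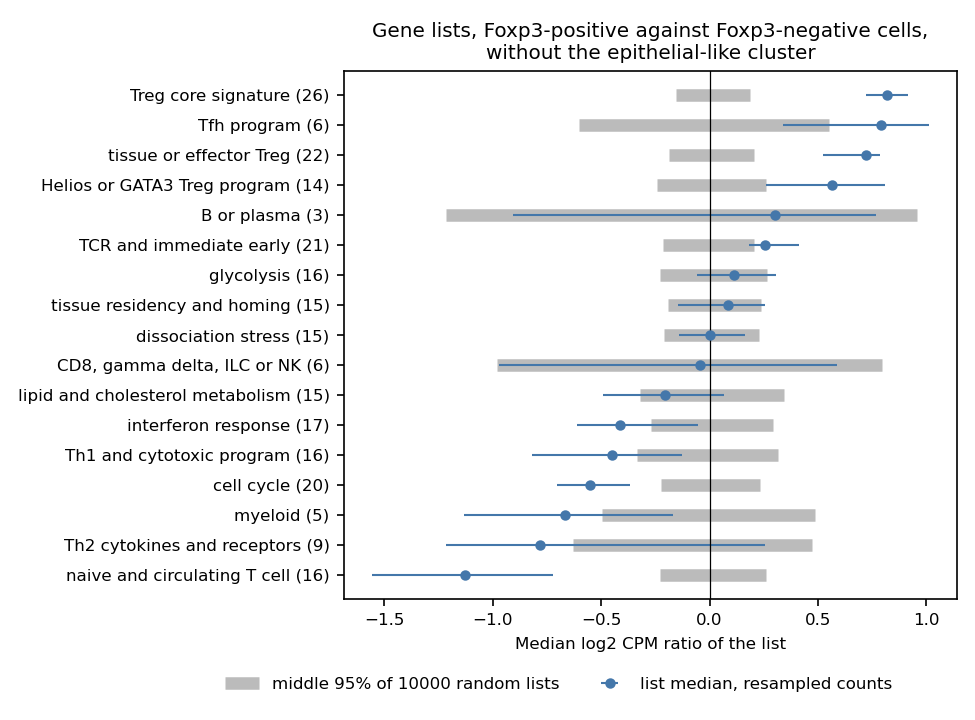
Median log2 CPM ratio of each gene list, Foxp3-positive against Foxp3-negative cells, without the 14 epithelial-like cells (326 against 701 cells). Points with bars are medians with 95% intervals for counting error, grey bars are the middle 95% of 10000 random lists matched on expression, and numbers in brackets are measured genes. The Treg core list lies at 0.82 and the naive list at -1.13, both outside the grey bars.

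The 12 genes with the highest ratios were Penk, Gabarapl1, Lag3, Tcn2, Cpm, Btd, Adam17, Fam216a, Ube2f, Ikzf4, Ddx52 and Iws1, at log2 ratios from 1.51 to 1.92. Penk stood at 239 against 63.2 CPM (1.92, 1.47 to 2.37; capped 0.87), Lag3, an inhibitory receptor gene, at 67.1 against 19.5 CPM (1.79, 0.95 to 2.66), and Ikzf4, which encodes Eos, at 101 against 35.0 CPM (1.52, 0.88 to 2.18). After thinning the intervals of 8 of the 12 included 0: Gabarapl1 (0.27, -2.21 to 2.19), Ddx52 (0.07, -1.69 to 1.52), Ikzf4 (0.30, -1.49 to 1.78), Ube2f (0.64, -0.99 to 2.05), Cpm (0.86, -0.65 to 2.21), Btd (1.14, -0.55 to 2.67), Iws1 (1.14, -0.19 to 2.37) and Lag3 (1.41, -0.34 to 3.01). With the sides set by Treg-like clusters in that way, Lag3 (-0.33), Btd (-0.46), Ddx52 (-0.12) and Cpm (-0.045) turned direction. The 12 lowest were Muc2, Klk1, Col1a2, Guca2a, Col3a1, Tspan1, Car1, Selenbp1, Sparc, Krt8, Muc3 and Agr2, which include genes of epithelial and stromal cells. None of their 12 capped intervals left out 0, and Krt8 (0.22) and Agr2 (0.37) turned direction without the epithelial-like cluster. Muc2 stood at 5.92 against 1241 CPM (-7.71), and its capped interval (-3.99 to 0.19) included 0. Without the epithelial-like cluster the 12 lowest instead included Igfbp4 (-4.31, -7.38 to -2.41), Ccr7 (-3.15), Tcf7 (-3.12), H2-Eb1, Prkar2a, Lyz2, Pde7a, Nsg2, Prpf39, Bcl2 (-2.16, -3.34 to -1.16) and Rhno1. H2-Eb1 and Lyz2 came from 5 and 6 cells. The highest 12 then took in Sdcbp2 (2.0, 1.39 to 2.63), Slc25a20 (1.60) and Irak2 (1.48) in place of Tcn2, Ddx52 and Iws1.

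**Figure D4:**
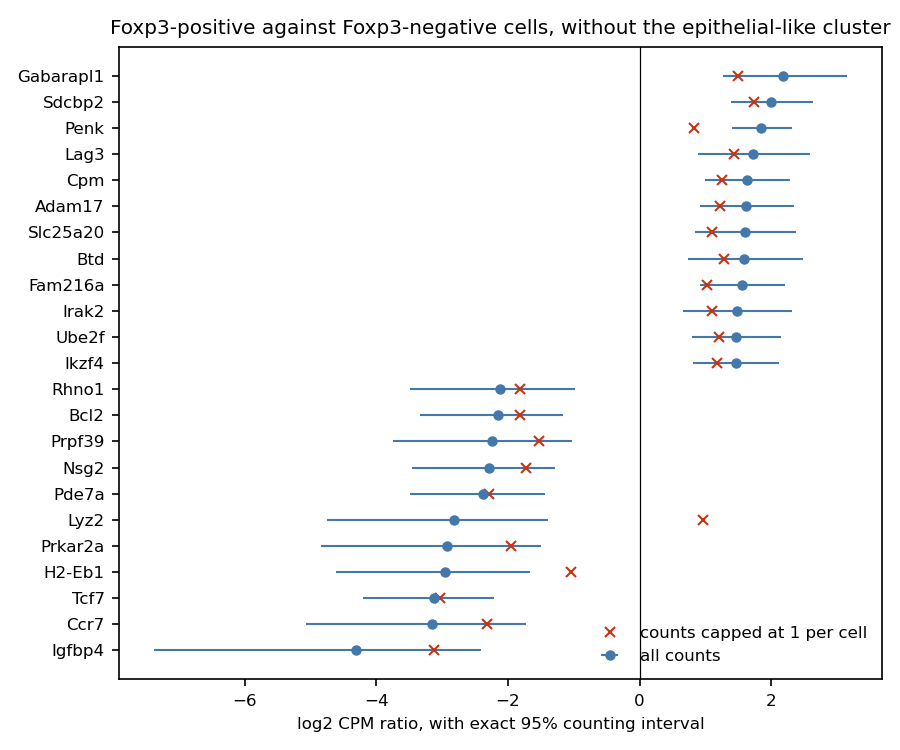
Log2 CPM ratios of the 12 highest genes and 11 of the 12 lowest, Foxp3-positive against Foxp3-negative cells, without the 14 epithelial-like cells. Dots with bars use all counts, with exact 95% intervals, and crosses use counts capped at 1 per cell. Gabarapl1 is highest at 2.18 and Igfbp4 lowest at -4.31, and the cross of Lyz2 lies on the other side of 0 at 0.96.

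Most Treg markers were also detected in more of the Foxp3-positive cells when every cell was thinned to 500 counts, which left out no cell. Izumo1r differed little, at 8.26% (5.51 to 11.8) of Foxp3-positive and 7.42% (5.61 to 9.60) of Foxp3-negative cells. Ctla4 was detected in 50.8% (45.2 to 56.3) of Foxp3-positive and 28.3% (25 to 31.8) of Foxp3-negative cells, and Ikzf2 in 32.4% (27.4 to 37.8) and 15.7% (13.1 to 18.6). Il10 was detected in 30.6% (25.6 to 35.9) and 10.8% (8.60 to 13.3), Gzmb in 22% (17.6 to 26.9) and 7.56% (5.73 to 9.75), and Il2ra in 12.8% (9.42 to 17.0) and 5.60% (4.03 to 7.55). Tcf7 was detected in 0.306% (0.00774 to 1.69) and 7.42% (5.61 to 9.60). Cd4, by which both sides were sorted, was detected in 19.9% (15.7 to 24.6) and 20.9% (17.9 to 24.0). Unthinned, Ctla4 was detected in 75.5% and 41.6%, Ikzf2 in 49.8% and 26.5%, Il10 in 44.0% and 16.7%, Il2ra in 27.2% and 12.7%, and Cd4 in 41.0% and 38.0%, so the order of Cd4 changed with thinning. In the naive-like cluster, which should lack most Treg products, unthinned Ctla4 was detected in 7.48%, Ikzf2 in 1.87% and Il10 in 0.935% of cells.

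Cells with a count of Il17a or Ifng, the cytokine genes of Th17 and Th1 cells, were few. Il17a was detected in 9 cells (0.865%, 0.396 to 1.63) and Ifng in 30 (2.88%, 1.95 to 4.09). Ifng was detected in 8.97% of the Th1-like cluster, so at this depth these numbers do not bound the number of Th17 or Th1 cells. Among Foxp3-negative cells 9 had Il17a without Ifng and 25 had Ifng without Il17a, and a side needed 10 cells. With no minimum on cells 10 stood against 28, the Th1 and cytotoxic list lay at -0.98 (-1.57 to -0.42, 5.41st percentile, 6 of 6 lower) and the cell cycle list at -1.61 (-1.91 to -0.40, 0.21st percentile, 7 of 7 lower, 2 of them at the floor). With capped counts these medians were -0.22 and -0.39. When cells with Il17f were counted with those with Il17a, 12 cells stood against 25, with median depths of 1687.5 and 1269 counts. Of the 12 cells 1 was epithelial-like, and their side held 28025 counts with it and 21045 without it. Values without it were added after seeing the data. The Th1 and cytotoxic list was then lower in the Il17a or Il17f cells, with 6 of 6 measured members lower (median -1.91, -2.43 to -1.30, 0.51st percentile), and at -1.50 (-2.01 to -0.88, 1.16th percentile) without that cell. Of its 6 ratios 3 rest on a side of 0 counts set to the floor, in all 3 versions, so these medians are partly bounds. Without it Nkg7 stood at -1.34 (-3.09 to 0.08) and Cxcr3 at -1.78 (-4.97 to 0.37), both with intervals that included 0. Gimap4 (-5.05, -10.38 to -2.52) and the class I genes B2m (-1.39, -1.91 to -0.91) and H2-K1 (-1.18, -1.70 to -0.69) were lower without it, and Ctla4 was higher (2.17, 0.91 to 3.57). The TCR and immediate early list lay at -0.71 (-1.02 to -0.16, 2.27th percentile) with that cell and at -0.31 (-0.58 to 0.18, 12.4th percentile) without it, but at 0.27 (-0.25 to 0.57, 87.8th percentile) for the 10 against 28 cells. The cell cycle list, in contrast, lay at 0.12 for the 12 against 25 cells (-0.43 to 0.58, 7 of 11 higher) and at 0.44 (-0.08 to 0.92, 8 of 11 higher) without the epithelial-like cell. With capped counts these medians were -0.70 and -0.60, so this contrast with the 10 against 28 cells did not hold. The largest ratios with that cell, for Muc2 and Agr2, came from 1 cell. With counts capped and that cell kept, the Th1 list lay at -0.79 (-1.64 to 0.19) and the interval of Ctla4 included 0. Those of B2m and H2-K1 also did, but these genes had 6571 and 6569 counts over the 1041 cells. A cap of 1 per cell can hide a difference in level for such genes, so their capped intervals do not decide. All of these values describe few cells.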

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

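The tests of several counts per molecule and of free RNA, the Poisson draws, the 10 repeated thinnings and the counts capped at 1 were chosen after the result was seen. The labels give 1 group, so no biological explanation was tested for either pattern.

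A signal outside the main measurement was found in 389 barcodes with over 80% mitochondrial counts, which entered no comparison except the alternative with no minimum on cells. Their median was 90 counts and their highest 3714, and 15 of them had at least 500 counts. Across 13 mitochondrial genes their profile had r = 0.960 with that of the analysed cells, a value across genes, which are not independent replicates. They held 4798 other counts in all. The 914 barcodes under 500 counts held 6.85% of all counts.

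Counts of a gene varied between cells more than Poisson counts would. With cells thinned to 500 counts, the median variance-to-mean ratio was 1.35 over 1631 genes. Without thinning, 4931 low genes had 24.1 entries of 2 counts per 100 entries of 1, against 2.83 under a Poisson law with 1 mean per gene. Differences in depth and class between cells also raise the unthinned number, so that contrast is not a measure of the excess alone. A mixture of cell classes as the whole cause is argued against, since the ratio was 1.32 within the naive-like cluster alone. Several counts per captured molecule may contribute, but whether the excess is general stays open. The 10th percentile of the ratio over genes was 1.14 over all cells, where classes mix, and 0.953 in the 107 naive-like cells, while Poisson draws with the same means gave 0.945 and 0.887. Bursts of transcription in single cells could also raise the ratio and were not tested.

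The Treg core list was higher in Foxp3-positive cells (median 0.88, 0.77 to 0.97). Deeper cells being more often Foxp3-positive is argued against as the whole cause, since the median was 0.59 (0.50 to 0.85) with each cell thinned to 500 counts before gating, and 0.48 to 0.88 over 10 thinnings. Free RNA that reaches all cells alike would give similar shares of cells with Foxp3 in the naive-like and Treg-like clusters. The shares were 5.61% (2.09 to 11.8) of naive-like and 52.1% (44.8 to 59.3) of Treg-like cells, so that prediction was not met. Foxp3 was not kept out of the genes used for clustering, and it was among the markers that named the Treg-like cluster. Neither share is therefore independent of Foxp3, and they do not decide on free RNA by themselves.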

How the results depend on the processing

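The settings chosen after the data were seen were the leading-gene minimums, scaled genes, a second other seed, the comparisons without the epithelial-like cluster, capped counts, division by the median ratio, all settings of the Gata3 and Ikzf2 comparisons, and the 10 repeated draws. No paired analysis was possible because the barcodes carry no sample. For the same reason edgeR with and without TMM, DESeq2, count filters, the replicate block, leaving out each replicate, camera, fry and sample agreement were not run. Of the values that answer a comparison, 41 stayed within their interval and 59 moved. Most of them were shares of clusters or of cells with a marker, for which no change of direction could be counted, and some shares fell to 0%. None of the list medians among them changed direction. Of numbers of cells, 7 stayed within 1.5 times the first number and 2 moved. Of the others, 1509 stayed, 306 moved and 50 changed direction. A change of direction was counted only where the first interval left out 0, so changes of sign in other values are among those that stayed or moved. Lists left with too few usable genes under a setting gave no value there. The cause was not tested where none is given.

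The shares of named clusters depended on the clustering. At resolution 0.6 the shares were 33.5% Treg-like, 32.1% naive-like, 34.4% unnamed and 0% Th1-like, cycling-like and epithelial-like. At resolution 1.5 they were 0% Treg-like, 5.76% Th1-like and 79.3% unnamed. With at least 1000 counts per cell they were 38.1% Treg-like, 8.21% naive-like, 12.5% Th1-like, 41.2% unnamed and 0% cycling-like and epithelial-like. With no minimum on cells 100% were unnamed and every named class stood at 0%. With leading genes in at least 20% of a cluster they were 51.5% Treg-like, 0% Th1-like and 32.9% unnamed, and at 25% they were 36.3%, 0% and 48.1%. With no detection minimum Th1-like was 15.4%, myeloid-like 15.2% and unnamed 35.4%. With scaled genes they were 30.3% Treg-like, 6.72% naive-like, 63.0% unnamed and 0% Th1-like, cycling-like and epithelial-like. With another seed they were 13.2% naive-like, 0% Th1-like and 62.6% unnamed. With a second other seed they were 25.5% Treg-like, 12.6% naive-like, 16.9% Th1-like and 40.2% unnamed. With doublets kept Th1-like was 0% and unnamed 65.0%.

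The Treg core median of the Foxp3 comparison (0.88) stayed above 0 under every alternative that gave a value. It moved to 1.01 with no minimum on cells, 0.59 after thinning to 500 counts, 0.71 in cells at odd positions, 0.76 with 2 or more Foxp3 counts and 0.71 with counts capped at 1. It stayed within its interval, at 0.82, without the epithelial-like cluster. When Treg-like clusters found on a random part of the counts were compared with all other cells on the rest, in place of the Foxp3 gate, it was 0.97. That draw was the lowest of the 6 among 10 draws that gave a Treg-like cluster (0.97 to 1.2), and 4 draws gave none. Such clusters were named by Treg markers, most of which are members of this list. A raised median there follows from the naming and is no separate support.

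Results of the Foxp3 comparison that changed direction were mostly low genes and genes of other cell types. With cells at odd positions the cell cycle list was 0.17, Krt8 0.20, Lgals4 1.88 and Krt19 2.88. Without the epithelial-like cluster Krt8 was 0.22 and Agr2 0.37. With capped counts the myeloid list was 0.44, Agr2 0.42, Lyz2 0.27, H2-Aa 1.23 and Cd74 0.74. After thinning the myeloid list was 0.34, H2-Aa 0.34, Tox -0.71, H2afz -0.12 and Tuba1b 0.045. With Treg-like clusters against all other cells on a random part of the counts, which changes both the groups and the counts, Lag3 was -0.33, Cpm -0.045, Btd -0.46, Ddx52 -0.12, S100a6 -0.070, Slamf6 -1.27 and Sh2d1a -1.42.

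In the Gata3 comparison within Foxp3-positive cells, thinning moved the Helios or GATA3 list to 0.12, the lowest of 10 draws, which reached 0.85. The value of 0.12 rested on 8 usable genes of the list. After thinning Arl1 was -0.64, Rgcc -0.32, Mpp1 0.041, Cst3 0.10, Il2ra -0.14 and Maf 0.044. With capped counts Junb was -0.13 and Cst3 0.047, and in cells at even positions Cst3 was 0.059. In the Ikzf2 comparison, thinning gave 0.30 for the cell cycle list, -0.13 for Tox, -0.94 for Tpp2, -0.36 for Arhgef3, -0.46 for Gimap8, 0.13 for Smndc1, 0.60 for Naa15 and 0.0042 for Rgs1. For Gata3 in Foxp3-negative cells, thinning gave -0.42 for the cell cycle list, -0.53 for Tubb5, -1.36 for Ccna2 and 0.64 for Lyz2, and capping gave 0.025 for Avl9.

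The smaller side of the Il17a and Ifng comparison (9 cells) held 5 after thinning and 3 at odd positions. With no minimum on cells it held 10, and the Th1 list then lay at -0.98 (5.41st percentile). With Il17f added, Cox8a was -0.12 and Tmsb4x 0.20 without the epithelial-like cell, and with capped counts Cox8a was -0.78, Actg1 -0.17 and Lgals1 -0.21. Detection in Foxp3-positive cells rose with depth: at 300 counts, 1000 counts and unthinned, it was 9.17%, 22% and 27.2% for Il2ra, 37.6%, 71.8% and 75.5% for Ctla4, and 19.6%, 40.8% and 49.8% for Ikzf2. The values at 1000 counts cover only cells with at least 1000 counts, while the others cover all Foxp3-positive cells.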

Other observations

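All the gates on Gata3 and Ikzf2 were chosen after the data were seen, and the tests of depth and of heat shock genes were set out before their results. The epithelial-like cells were left out of these comparisons.

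Among Foxp3-negative cells, those with Gata3 carried more Th2 transcripts. Gata3 was detected in 565 of 1041 cells (54.3%, 51.2 to 57.3). The 367 Foxp3-negative cells with Gata3 were set against 334 without (median depths 1297 and 1128.5 counts). The sides differ in their clusters, since Gata3 was detected in 80.7% of Treg-like, 87.3% of cluster 2 and 26.2% of naive-like cells. Foxp3-negative means only that no Foxp3 count was found at this depth. Foxp3 was detected in 52.1% of Treg-like and 48.7% of cluster 2 cells, and the rest of them are among the Foxp3-negative cells. The values below can therefore not be assigned to cells other than Tregs. The Th2 list was higher in 7 of 7 measured members (median 1.57, 0.64 to 2.03, 99.97th percentile; 1.38 after thinning), with Il4 at 1.73 (0.11 to 3.76) and Il1rl1, the IL-33 receptor gene, at 1.09 (0.31 to 1.94). Areg stood at 220 against 47.1 CPM (2.23, 1.54 to 2.99), Klrg1 at 568 against 172 CPM (1.72, 1.35 to 2.11) and Gfi1, which encodes a transcriptional repressor, at 86.4 against 14.1 CPM (2.61, 1.38 to 4.13). The Helios or GATA3 list lay at 0.68 (0.52 to 1.28, 12 of 13 higher). The Treg core list, which holds most genes of the Helios or GATA3 list, lay at 0.51 (0.37 to 0.78, 20 of 24 higher). Naive genes were lower (median -1.25, -1.52 to -0.92, 14 of 16 lower), with Igfbp4 at -3.68 (-5.05 to -2.56) and Ccr7 at -2.33 (-3.29 to -1.47). After thinning the intervals of Il4, Il1rl1 and Ccr7 included 0. The cell cycle list was 0.55 (0.32 to 0.71) but -0.42 after thinning. The dissociation stress list was also higher in these cells (0.31, 0.16 to 0.43, 99.6th percentile, 11 of 15 higher; 0.08 with counts capped at 1). Lists of other cell types moved too: the myeloid list was -0.72 (-1.26 to -0.14, 0.25th percentile, 4 of 5 lower; 0.47 capped), and the CD8, gamma delta, ILC or NK list was -0.99 (-1.82 to 0.04, 2.06th percentile, 3 of 4 lower).

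Among Foxp3-positive cells, 163 with Ikzf2 and 163 without did not differ beyond counting error in Ctla4 and Il10. Their log2 ratios were -0.05 (-0.23 to 0.14) and -0.04 (-0.30 to 0.23). Foxp3 stood at 0.05 (-0.17 to 0.27), but a Foxp3 count was required on both sides, so this ratio does not compare its level freely. The Helios or GATA3 list lay at 0.33 (-0.02 to 0.69, 99.2nd percentile, 8 of 12 higher), and the cell cycle list at -0.32 (-0.82 to -0.11, 1.56th percentile) but 0.30 after thinning. The TCR and immediate early list was higher in cells with Ikzf2 (median 0.46, 0.29 to 0.64, 99.99th percentile, 17 of 19 higher; 0.33 after thinning). Gata3 stood at 2133 against 1245 CPM (0.78, 0.57 to 0.98), and at 0.12 after thinning. Mmp9, a secreted protease gene, stood at 65.6 against 237 CPM (-1.86, -2.73 to -1.05), and at -0.62 after thinning. Both thinned intervals included 0.

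Foxp3-positive cells with Gata3 (197, median 1415 counts) carried more of the Helios or GATA3 list than those without (129, median 1159 counts), with a median of 0.75 (0.41 to 1.23) and 8 of 12 measured members higher. Areg stood at 246 against 34.4 CPM (2.84, 1.65 to 4.33) and Klrg1 at 942 against 390 CPM (1.27, 0.89 to 1.67), and after thinning these were 2.17 (0.50 to 4.23) and 1.03 (0.33 to 1.75). Deeper cells being more often Gata3-positive may account for the list's difference. After thinning the median was 0.12 (-0.12 to 0.71), the lowest of 10 draws from 0.12 to 0.85. It rested on 8 usable genes, against 12 unthinned, so depth stays open. If stress during tissue dissociation were the cause, the heat shock genes were predicted to reach at least the median of the list. The 7 heat shock genes had a median of 0.22 (-0.07 to 0.39), below the unthinned 0.75 of the list, so that prediction was not met. Their interval lay on both sides of the bound set beforehand for the opposite prediction, so stress as a part of the difference stays open. The TCR and immediate early list was higher in the same cells (median 0.65, 0.42 to 0.79; 0.68 after thinning). The dissociation list, which shares genes with it, lay at 0.24 (0.07 to 0.43), and at 0.073 with counts capped at 1. The Th1 and cytotoxic list was lower in these cells (-0.61, -0.89 to -0.04, 1.01st percentile, 8 of 10 measured members lower; -0.47 with counts capped at 1). The myeloid list lay at 1.27 (-0.15 to 2.39, 99.4th percentile, 2 of 3 measured genes higher), and at 0.05 with counts capped at 1.

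Ighm, the gene of the immunoglobulin mu heavy chain, was detected in 306 cells (29.4%, 26.6 to 32.3), while Cd79a was detected in 1, Ms4a1 in 3 and Igkc in 9. With cells thinned to 500 counts, Ighm was detected in 18.0% (14.0 to 22.6) of Foxp3-positive and 15.5% (13.0 to 18.4) of Foxp3-negative cells. The cytotoxic genes Gzmk and Prf1 were detected in 0 of 1041 cells, which allows up to 0.354% of cells with a count. Il4 was detected in 18 cells, Il5 in 6 and Il13 in 9.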
